A study of Mus musculus with 2 samples.

How the data were processed

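Chromatin accessibility was measured in 2 libraries of sorted mouse B cells, 1 from Smarca5 knockout and 1 from control donors. Per the file headers, the fragment files were made with Cell Ranger ARC 2.0.2 on its mm10 reference package 2020-A. The deposited values are counts: each line is a unique fragment with its cell barcode and the count of read pairs that support it, with no normalization, per the file headers. The files hold barcodes of cells and of empty droplets together and no mitochondrial contig. The gene expression part of the experiment was not used here. The files held 73655208 knockout and 92316347 control fragments, of which 54371 and 60681 lay on contigs outside chromosomes 1 to 19, X and Y and were left out.

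Gene positions and symbols came from a RefSeq table of the same build, GRCm38.p6, that gives no strand. The start site of each of 21887 protein-coding genes was therefore taken as the gene end with more fragments within 1000 bp over both libraries, and 10802 genes had a clear end. The interferon gene Mx1 was missing from the table.

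Before the data were examined, the cell calling rule, the size rules, the gene lists, the cell type markers, the named-gene rule and the main alternatives were fixed. Cells were barcodes with at least 1000 fragments, above the valley in the histogram of fragments per barcode (2005 in the knockout and 1128 in the control library), and with start site enrichment of at least 4. Barcodes above 4 times the library's median were removed as doublets, 78 and 61 barcodes. No doublet caller was used. Called cells held 74.7% and 78.3% of all fragments.

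Accessible regions of 500 bp were called after drawing 55012599 fragments from each library, by Poisson enrichment of cut sites over the local 10000 bp with at least 4-fold enrichment, which gave 73688 regions. Sets called in each library alone overlapped by at least 250 bp at 83.5% of knockout and 85.6% of control regions.

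Cells of both libraries were clustered by latent semantic indexing with 31 components, then 20 nearest neighbours and Leiden clustering at resolution 0.6. The first component was left out because its correlation with depth was 0.97. The second, with a correlation of 0.66, was kept in the main clustering. A cluster was named from markers at least 1.5 times above other cells, with at least 3 needed, and the list with the most such markers gave the name. A name of a cell that is not a B cell also needed pan B cell markers at least 1.5 times below other cells in the median. A cluster joined the pool when at least 3 resting B cell markers were 1.5 times above the named clusters and fewer than 3 markers of another list were raised. No named class held the 200 cells of both libraries that the plan asked for. Clusters 0, 2, 3, 4 and 6 were therefore pooled, and the rule that keeps a cluster with 3 or more markers of another list out of the pool was set after seeing the data.

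Ratios are log2 of knockout over control fragments, scaled to all promoter or all region fragments, with exact conditional binomial intervals. Shares have exact Clopper-Pearson intervals and rates exact Poisson intervals, at 95%, and all cover counting error only. Promoter windows reach 1000 bp either side of the start site. No p-values were computed, because cells of 1 library are not replicates. Gene lists were described by the percentile of their median among 10000 random lists matched on mean promoter fragments. Named promoters are the 10 highest and 10 lowest ratios with a mean of at least 200 fragments whose sign was kept under every scaling, up to 4 members per list, and the 5 highest and lowest distal regions with a mean of at least 100 fragments. The text prints only part of the promoters, list members and regions that this rule selects.

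Distances were counted between midpoints of 150 to 200 bp fragments more than 1500 bp from the centres of accessible regions, with at most 5 per position. Of 1063766 bins of 2000 bp, 16907 with over 5 times the chromosome mean were left out. The analysis was run in 3 forms: an exploratory form, a form with all bins and the form with dense bins left out, which was chosen after the form with all bins was seen. The definitions of the fragment length peaks and of the flanking peaks around distal regions were also changed after the data were seen.

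The steps were tested on simulated data. For the promoter comparison of whole libraries, 100% of 98 promoters changed by 2-fold and 99.0% of 98 changed by 1.7-fold passed the size rule, and 0% of unchanged ones did, among 11725. For the region comparison of whole libraries, among 46924 regions, 100% of 93 changed by 2-fold and 93.8% of 97 changed by 1.7-fold passed, and 0.0278% of unchanged ones. For the gene lists, 7.0% of 200 unshifted random lists fell outside the central 95%, more than the nominal share. For the distances, simulated spacings of 185, 195 and 205 bp were found as 185.5, 195.5 and 205.5 bp. The simulated arrays were regular, so this accuracy does not carry over to the libraries. Random subsets of the pooled knockout cells gave fitted spacings of 193.5 and 177 bp.

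Motif classes, nucleosome phasing at CTCF sites, every GC correction and clustering without CTCF motif regions were planned and not run, because no genome sequence was used here. Alternatives that were run changed scaling, windows, minimum counts, fragment classes, region sets, cell calling, depth, clustering resolution and seeds. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.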

Results

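The data are the chromatin accessibility part of a 10x Genomics multiome experiment on mouse lymph node B cells, in which the transposase Tn5 cuts open DNA and each sequenced fragment keeps the barcode of its nucleus. Donor B cells carried the B1-8hi heavy chain, which binds the hapten NP, and were transferred to wild-type mice that were then immunized with NP-KLH. The cells were sorted on day 5. There are 2 groups with 1 library each. In the knockout library the donor B cells carried floxed Smarca5 and CD23-Cre, and the control library holds the matching control cells. Smarca5 encodes the ATPase of the ISWI chromatin remodellers, which slide nucleosomes into evenly spaced arrays. The knockout library held 73655208 fragments and the control library 92316347. From these, 6583 and 7796 cells were called, with medians of 7002 and 8639 fragments per cell. Enrichment of fragments at transcription start sites had a median of 52.7 per knockout cell and 55.8 per control cell. No group has a replicate, so no difference below could be set against a spread between animals. Intervals in parentheses are 95% intervals that cover counting error only.

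Smarca5 itself was read first, because it checks the labels. The gene lies on chromosome 8 from 80699943 to 80739459 (mm10). Its promoter held 3806 fragments in the knockout library and 5005 in the control library, a log2 ratio of -0.00 (-0.06 to 0.06) after scaling to all nuclear fragments. The gene body outside the promoter held 1137 and 1107 fragments, a log2 ratio of 0.43 (0.31 to 0.55). Windows of 500 bp along Smarca5 were scored only where the control library had at least 20 fragments, which left 229 overlapping windows. The lowest ratio among these was -0.77 on the log2 scale, from 9 against 20 fragments. Among 1364 genes of similar length and depth, 94.1% had a lower minimum. No deleted segment could be read from the scored windows, and the rest of the gene was too sparse to score. Exon positions were not used here, so these data do not check the genotype labels.

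Germinal centers are the sites where activated B cells mutate and select their receptors, and whether B cells without Smarca5 form them at day 5 was the first question. Germinal center-like cells were rare among called cells of the knockout library and frequent in the control library, and the size of this difference depended on the calling threshold. Cells were clustered on their accessible regions. Cluster 5 was named germinal center-like from preset markers such as S1pr2, which retains cells in germinal centers. Bcl6, the transcription factor of this state, was on the preset list but was lower in cluster 5 than in the pooled clusters, described below. For Bcl6, control cells had 111 CPM (gene body and 2000 bp upstream, scaled to nuclear fragments) in cluster 5 and 126 in the pooled clusters. Knockout cells had 63.4 and 109. Cluster 5 held 44 of the 6583 knockout cells, or 0.668% (0.486 to 0.896). In the control library it held 1605 of the 7796 cells, or 20.6% (19.7 to 21.5). Antibody-secreting-like cells of cluster 7, named from markers that include Jchain, were 2 knockout cells, or 0.0304% (0.00368 to 0.110), and 189 control cells, or 2.42% (2.09 to 2.79). The T cell gene Cd28 was also among the leading genes of cluster 7. Cluster 5 had 6 raised markers of the germinal center list, 3 of the stromal list and 2 of the T cell list, and its 10 leading genes held no marker of any list.

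The germinal center-like share moved with the clustering settings in the knockout library, from 0.197% to 4.06% over 13 alternatives. In the control library it ranged from 13.4% to 21.3%. The control share was 30.8 times the knockout share in the main clustering and 5.14 to 69.2 times over all settings. After each cell was thinned to 4000 fragments, which left out 1603 knockout and 1683 control cells, the shares were 0.321% and 18.7%. Without the 2101 regions within 50 kb of any marker gene they were 1.40% and 20.9%.

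Shallow barcodes moved the knockout share most. The calling threshold, set at the valley of each library's histogram, was 2005 fragments in the knockout and 1128 in the control library. With a minimum of 1000 fragments in both, a setting added after the other results were seen, germinal center-like cells were 330 of 8137 knockout cells, or 4.06% (3.64 to 4.51), and 1650 of 7911 control cells, or 20.9%. Below 2005 fragments they were 14.5% (12.8 to 16.3) of 1671 knockout and 28.9% (25.6 to 32.4) of 702 control barcodes. From there to 4000 fragments they were 3.74% and 27.9%, and above it 0.576% and 18.7%. The 242 shallow knockout barcodes had 8 of 14 germinal center markers above the pooled clusters at that depth, among them S1pr2 at 40.3 against 16.5 CPM and Basp1 at 37.2 against 16.0, each from few fragments. The 203 shallow control barcodes of this class also had 8 of 14 above, though not the same ones. The median log2 ratio of the markers over the pooled clusters was 0.24 in both libraries. Median enrichment at start sites of the 242 knockout barcodes was 44.6, against 57.6 in the knockout pooled clusters. In the control library these values were 56.2 and 59.6. Knockout cells with little DNA recovered and damaged nuclei were therefore not told apart. Antibody-secreting-like cells were 0.406% of knockout cells under this minimum.

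**Figure D1:**
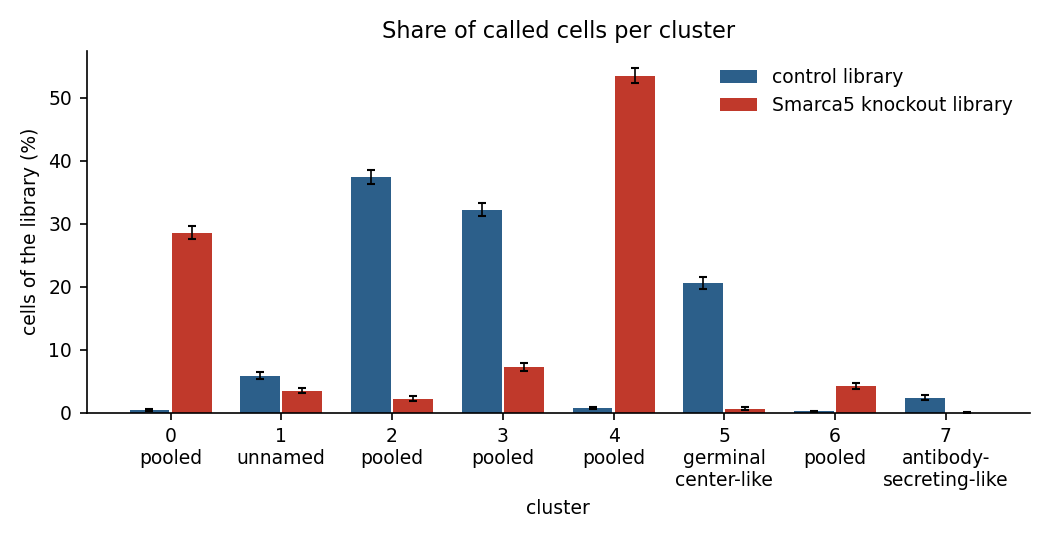
Share of each library's called cells (y axis, percent) in clusters 0 to 7 (x axis), for the control and the Smarca5 knockout library; error bars are exact 95% binomial intervals. Cluster 5, germinal center-like, holds 20.6% of the control cells and 0.668% of the knockout cells.

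The identity of the 44 knockout cells in cluster 5 stayed open. Their fragments fell in regions typical of control germinal center-like cells at 2.70% (2.57 to 2.83), against 2.85% in control cells of the cluster that had no part in choosing the regions. The 44 cells had been placed in the cluster on accessible regions that include these, so the selection itself brings the values together. Single markers, however, were below control cells of the cluster, by differing amounts and from few fragments. Basp1 had 12.7 CPM (gene body and 2000 bp upstream, scaled to nuclear fragments) in these 44 cells, from 3 fragments, and 79.9 in control germinal center-like cells. Cells of the pooled clusters, described below, had 15.9 in the knockout and 20.1 in the control library. Mybl1, a transcription factor of dividing germinal center cells, had 38.0 CPM in the 44 cells and 131 in control cells of the cluster. Nuggc, at 59.2, was the marker closest to control cells of the cluster, and lay between the pooled cells of the control library (55.0) and of the knockout library (66.5). Gcsam, at 12.7 from 3 fragments, stood above the pooled clusters, which had 3.47 in the knockout and 3.38 in the control library, and S1pr2, at 21.1, lay between the pooled cells of the knockout (14.7) and the control library (22.4). Of 14 markers, 11 were below the knockout pooled cells in the 44 cells. The 44 cells were also shallow, with a median of 2711 fragments. Their median enrichment at start sites was 31.7, against 55.4 in control cells of the cluster, and their median dinucleosome share 4.40% against 7.78%. Fragments under 120 bp had a median share of 58.6% against 51.4%, and chromosome X held 3.14% against 1.65% of fragments.

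Most remaining cells separated by library, though not all. Clusters 0, 4 and 6 were mostly knockout cells, and clusters 2 and 3 mostly control cells, with 622 of the 6306 pooled knockout cells. These 5 clusters held 95.8% of the knockout and 71.1% of the control cells and were pooled for comparisons inside the non-germinal-center cells. They carry no class name, because no list had more than 1 marker raised over the other cells in any of them, and naming took at least 3. Leading genes of cluster 0 included Il7r, of the T cell list. Those of cluster 2 were headed by the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d, and Cebpa, of the myeloid list, came at rank 7. Separation by library thus went along with a difference in Y-linked fragments. Cluster 1 had 4 markers of the myeloid list and stayed outside the pool. It got no name, because its pan B cell markers were not as low as a myeloid name required. It held 3.51% of the knockout and 5.87% of the control cells.

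Promoters asked which genes opened or closed in the knockout library. Over all called cells, Basp1 and S1pr2 of the germinal center program had lower promoter accessibility there, and the chemokine genes Ccl3 and Ccl4 had higher accessibility. The libraries also differ in their share of germinal center-like cells, so these ratios mix cell shares with differences inside cells. Among 11735 promoters with a mean of at least 200 fragments, 132 had a ratio of at least 1.5 in favour of the knockout library and 324 in favour of the control library. The ratio is a rule of size, not a test. Within the pooled clusters the counts were 95 higher and 173 lower of 11364 promoters.

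Among the lowest promoters in the knockout library were those of Atp11a, a phospholipid flippase gene, Mlf1, 2900026A02Rik and Tspan15. Atp11a had 63 knockout against 434 control fragments, a log2 ratio of -2.36 (-2.77 to -1.98). Atp11a in the pooled clusters had a log2 ratio of -0.43 (-0.99 to 0.12). Fbxl2, Trabd2b, Tmem211, Ephb3 and Zfp423 were also among the 10 lowest, between -1.95 and -1.87. Zfp423, a zinc finger gene that can oppose the B cell factor EBF1, was also lower in the pooled clusters, at -1.32 (-1.58 to -1.07).

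The highest promoter was that of Pla2g4a, the cytosolic phospholipase A2 that releases arachidonic acid, with 413 against 180 fragments and a log2 ratio of 1.62 (1.36 to 1.88). In the pooled clusters it was 1.47. Ccl3 and Ccl4, chemokines that activated B cells use to attract T cells, followed at 1.42 (1.22 to 1.61) and 1.38 (1.18 to 1.58). These genes lie close together on the chromosome, so their values may not be independent. Gm14137, S100a2, P3h2, Nsg2, Il18r1, Cd28 and Lgr5 completed the 10 highest, between 1.37 and 1.30. In the pooled clusters the 3 lowest promoters were the Y-linked genes Ddx3y, Uty and Eif2s3y, at -1.89, -1.80 and -1.72. Fragments from the Y chromosome come from cells of male animals only.

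**Figure D2:**
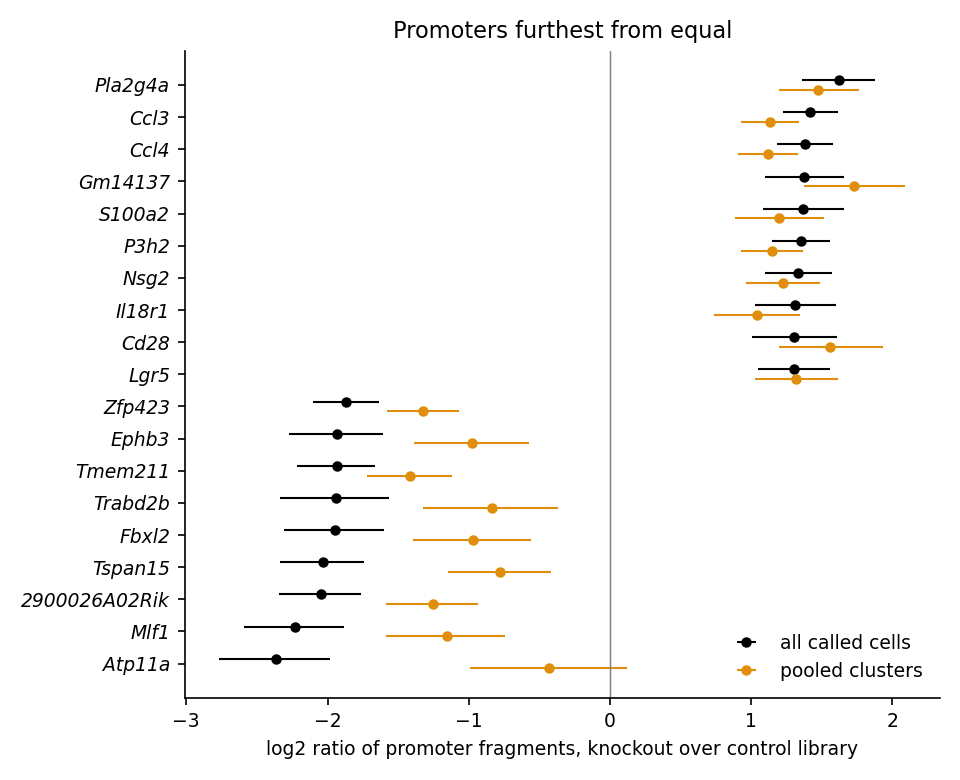
Log2 ratio of promoter fragments, knockout over control library (x axis), for promoters among the 10 highest and the 10 lowest (y axis) in all called cells and in the pooled clusters; error bars are exact 95% intervals for counting error. Atp11a lies at -2.36 in all called cells and at -0.43 in the pooled clusters.

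Promoters were also summarised over gene lists fixed beforehand. The median of the resting follicular B cell list was higher in the knockout library, with and without the germinal center-like cells, although its members differed. The median log2 ratio was 0.15 in all called cells, above all 10000 random lists matched on fragments, and 0.11 in the pooled clusters, at percentile 99.9. Ccr7, the receptor that guides B cells toward T cell zones, was at 0.62 (0.55 to 0.69) and at 0.38 (0.30 to 0.46) in the pooled clusters. Btla was at 0.47 and the egress receptor S1pr1 at 0.45. Fcer2a, which encodes CD23, went the other way, at -0.13 (-0.20 to -0.06) and at -0.38 (-0.45 to -0.31) in the pooled clusters. Pan B cell genes had a median of 0.09 (percentile 99.7), with Pou2af1 at 0.37 and Spib at -0.48. Memory B cell genes had a median of 0.14 (percentile 98.7), with Nt5e at -0.73 and Hhex at 0.35. In the pooled clusters their median was 0.08, at percentile 89.8, and with the gene activity window in all called cells the percentile was 73.4, both inside the central 95% of random lists.

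The germinal center list had a median of -0.15 in all called cells (percentile 2.66) and of -0.04 in the pooled clusters (percentile 41.1), both inside the central 95% of random lists. With the gene activity window in all called cells the list lay outside that range, at percentile 0.29. Its members moved apart. Basp1 was at -0.91 and S1pr2 at -0.89, while Rgs13 was at 0.92 (0.64 to 1.20). In the pooled clusters S1pr2 was still at -0.63 (-0.78 to -0.48), and Rgs13 at 0.91. In the central 95% of random lists also lay the medians of the antibody-secreting list (0.06), activated B cell list (-0.02, with Myc at -0.36), marginal zone or B1 list (0.06, with Bhlhe40 at 0.54), antigen presentation list (0.01, with Ciita at -0.45), T cell list (0.14) and myeloid list (-0.07, with Cebpa at -1.18 and Itgam at 0.87). The same held for cell cycle (0.00, with Ccnb2 at -0.37), ribosome biogenesis and MYC targets (0.04), chromatin factors (0.01, with Baz2a at 0.29), p53 targets (0.02, with Bcl2l11 at 0.31), interferon response (0.05, with Irf7 at -0.39), glycolysis (0.00, with Hk2 at -0.30) and the unfolded protein response (0.04, with Atf6 at -0.25). The NK cell, stromal and erythroid lists had fewer than 3 measured promoters, among them Prf1 at -0.35, Col1a1 at -0.47 and Klf1 at -0.01.

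Accessible regions asked where chromatin outside promoters differed. Distal sites accounted for most differences. Of 46911 regions with a mean of at least 100 fragments, 4732 were higher and 4144 lower in the knockout library by the ratio of 1.5. Promoter regions, within 1000 bp of a start site, made up 188 and 686 of these, and distal regions, further away, 4544 and 3458. The distal region furthest below the control library lay inside Wipf3, on chromosome 6 from 54460101 to 54460600, with 1 against 255 fragments, a log2 ratio of -7.64 (-12.95 to -5.15). Wipf3 is also among the leading genes of the germinal center-like cluster. A region near Nap1l1 had 1 against 204 fragments, a log2 ratio of -7.32 (-12.63 to -4.82). Others among the 5 lowest lay inside Pitpnc1 and near Pja1. The highest lay near Jcad, with 210 against 40 fragments and a log2 ratio of 2.75 (2.26 to 3.28), and near Hacd4, Nsg2, Slc20a1 and Setbp1.

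Within the pooled clusters, 3632 of 42991 regions were higher and 3172 lower in the knockout library, together 15.8%. Random subsets of equal size of the control cells differed at 0.993% of regions, control clusters 2 and 3 at 4.81%, and knockout clusters 0 and 4 at 5.51%. The clusters of each pair also differ in depth. Their medians were 12131 and 4579 fragments per control cell in clusters 2 and 3, and 13966 and 4935 per knockout cell in clusters 0 and 4. Most of these regions were higher in the deeper cluster, 1982 against 88 in the control and 2293 against 77 in the knockout pair. The region with the highest ratio lay near Rreb1, with 217 against 25 fragments and a log2 ratio of 3.05 (2.45 to 3.71), and the one with the lowest inside Sult2b1, with 34 against 213 fragments and a log2 ratio of -2.72 (-3.28 to -2.19). Among 1386 genes with at least 6 distal regions within 200 kb, a measure added after the data were seen, Thoc3 and Jcad had the highest median log2 ratios, at 1.27 and 1.21. Gpr183, the receptor that positions activated B cells, was at 0.73, although its own promoter was lower in the pooled clusters, at -0.44 (-0.59 to -0.29). The transcription factor gene Zeb2 was at 0.68. Rap1gap had the lowest, at -0.89.

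Nucleosome spacing is the direct readout of an ISWI remodeller in these data. Fragments that span more than 1 nucleosome were more frequent and longer in the knockout library. Fragments of 300 to 450 bp, the dinucleosome class, were 12.4% of knockout and 10.2% of control fragments. In the pooled clusters they were 12.4% and 10.7%. Fragments of 150 to 250 bp were 27.2% and 28.9%, and those under 120 bp, from open DNA, 44.0% and 45.1%. The last difference was within 0.1 percentage points in the pooled clusters, at 43.9% and 44.0%, and had the opposite sign over all barcodes, at 46.9% and 44.1%. The dinucleosome class peaked at 383 bp in the knockout and 358 bp in the control library, and the mononucleosome class at 163 bp in both.

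Distances between the midpoints of 150 to 200 bp fragments in the pooled clusters were read over the genome. The distance between neighbouring nucleosomes was not measured. The distance for 2 nucleosomes spans 2 repeat lengths, from a nucleosome to the second next one. It was 403 bp in the knockout and 386 bp in the control library. Random subsets of each library gave 397 and 401 bp against 385 and 388 bp. On 16 of 19 autosomes the distance was longer in the knockout library, with a median difference of 14 bp. The distances for 3 and 4 nucleosomes were 597 and 791 bp against 577 and 761 bp. With densely covered bins kept they were 564 and 741 bp against 566 and 743 bp, so only the first distance differed both ways. The fitted spacing per repeat was longer in the knockout library on 10 of 19 autosomes and does not separate the libraries. Control germinal center-like cells had a distance of 411 bp, longer than either pooled set.

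**Figure D3:**
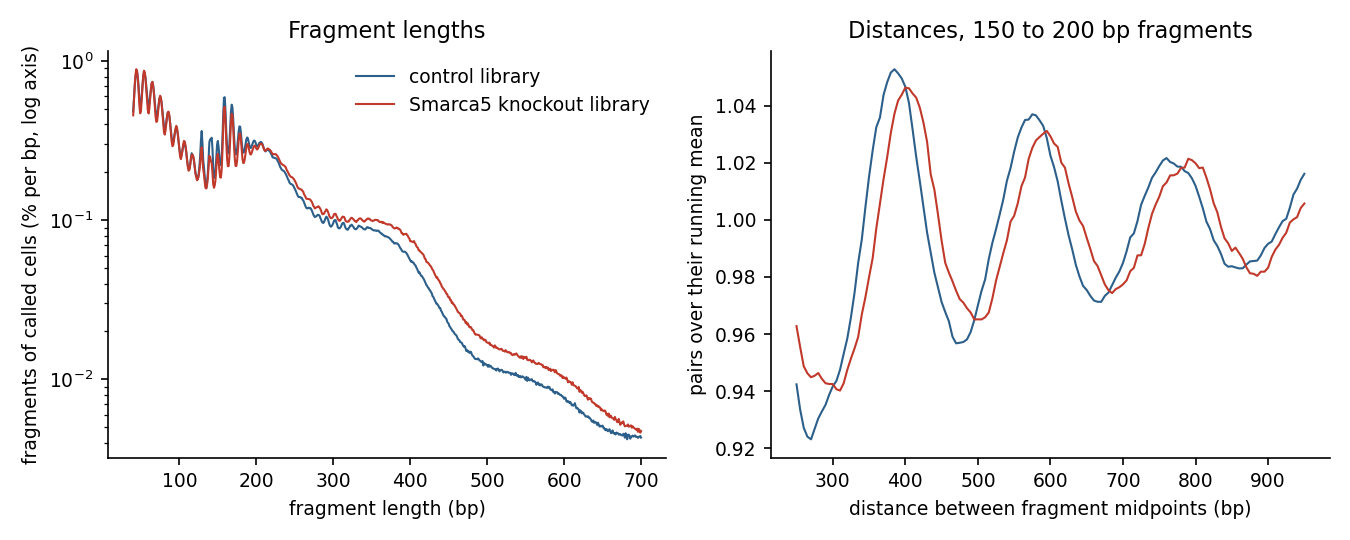
Left, share of called cells' fragments at each length (x axis, bp; y axis, percent per bp, log axis); right, number of fragment pairs in the pooled clusters at each midpoint distance (x axis, bp) over its running mean (y axis), each line 1 library. The first maximum on the right lies at 403 bp in the knockout and 386 bp in the control library.

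Around distal accessible regions, nucleosome-sized fragments were more frequent at the centre in the knockout library, and the flanking peaks were lower. Here distal regions were 53160 autosomal regions more than 5000 bp from a start site, without a minimum count. They are thus another set than the distal regions counted above, and were called on all called cells. In the pooled clusters, midpoints of 150 to 200 bp fragments at their centre were 5.77 times the level at the edge in the knockout library. In the control library they were 4.49 times that level. The first flanking peak reached 5.59 times, 117 bp from the centre, against 6.18 times, 124 bp from it. The position of that peak moved by a few bp between random subsets of the knockout library. The next flanking peaks lay further out in the knockout library, at 337 against 327 bp and at 496 against 485 bp. Random subsets of a single library differed by as much, with 328 and 317 bp in the control library for the nearer of these peaks and 511 and 496 bp in the knockout library for the farther. The ratio of centre to first flank was 1.03 in the knockout and 0.73 in the control library, and random subsets of each library gave 1.03 and 1.03 against 0.73 and 0.72. Fragments under 120 bp at the centre were 23.2 against 24.7 times the edge.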

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

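The tests of the mix of sexes and of the number of fragments on the nucleosome distances were planned before their values were seen. The bounds for the lower calling minimum were set before its result was seen, although the test was added after all other results. Thinning of cells was also planned beforehand, with its bounds set afterwards, and the other tests in this part were chosen only after the result was seen.

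Signals outside the comparisons stood above the control library in the knockout library. Xist, the RNA gene of the inactive X chromosome, had 33.8 CPM in the knockout and 21.2 CPM in the control library, while 4 Y-linked genes had 17.7 and 50.1 CPM. Both libraries therefore mix cells of male and female animals, in different proportions. The sex of the donors is not known, and donor cells were not told apart from cells of the recipient mice. Donor sex below therefore stands for the sex of the cells. Read pairs per fragment were 3.18 in the knockout and 2.52 in the control library.

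The smaller germinal center-like share in the knockout library was weighed first. Among cells of at least 4000 fragments the tables argue against unequal depth, since thinning to that number gave 0.321% against 18.7%. Shallower cells were left out before thinning, so the test does not cover them. With the lower calling minimum, cells from 2005 to under 4000 fragments gave 3.74% in the knockout and 27.9% in the control library. The tables also argue against donor sex, but only among cells that could be typed. Among cells with Xist fragments only the share was 0.0767% from 1 cell (0.00194 to 0.427) in the knockout and 25.7% in the control library. These knockout cells were deep, with a median of 10482.5 fragments, against 5915.5 in untyped knockout cells. Of the 44 knockout cells of the germinal center-like cluster 42 were untyped, so the test does not cover them. Loss of shallow cells in cell calling stays open and may account for part of the difference. With a minimum of 1000 fragments in both libraries the shares were 4.06% and 20.9%, a fold of 5.14 instead of 30.8. The added knockout barcodes were not told apart from damaged nuclei, and barcodes below that minimum were not clustered. A difference between donor animals stays open, because control cells with Xist fragments only had 2.41 times the share of those with Y fragments only. Loss of SMARCA5 may lower the share, or the DNA recovered from such cells, and with 1 library per group it cannot be told apart from the animals.

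The accessible regions that differ in the pooled clusters were weighed second. Counting error gives too few, with 0.993% of regions between random control subsets against 15.8% between libraries. Donor sex leaves no trace in the regions higher in the knockout library, with a median log2 ratio of -0.0068 between Xist and Y cells inside the control library against 0.77 between libraries. A difference of the whole library could come from preparation or from genotype. Knockout cells of cluster 1 carried 95.5% of the difference and those of clusters 2 and 3 only 38.8%, but clusters were drawn from the same regions, so this stays open.

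The longer distances between nucleosome-sized fragments were weighed last. The tables argue against the total number of fragments, since equal totals left a difference of 14 bp at the distance for 2 nucleosomes. These totals were drawn 1 time, and depth per cell was not made equal, so the test does not cover it. Control cells of the shallower cluster 3 had 395 bp and those of cluster 2 386 bp. Knockout cells of the shallower cluster 4 had 410 bp and those of cluster 0 407 bp. Donor sex stays open: cells with Xist fragments only differed by 5 bp, at the edge of the bounds set beforehand, while cells with Y fragments only had 389 bp in the knockout and 378 bp in the control library. A difference of the whole library, from preparation or from genotype, stays open as well. The distance was 388 bp in the 622 knockout cells of clusters 2 and 3 and 386 bp in control cells of these clusters. Random draws of 622 cells ranged from 370 to 438 bp in knockout clusters 0, 4 and 6 and from 359 to 411 bp in control clusters 2 and 3, so this number of cells does not separate the libraries. In dinucleosome share, another measure, 297 of those knockout cells carried 90.5% of the difference. Loss of the remodeller may lengthen the distances, and so may the preparation of the nuclei.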

How the results depend on the processing

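The alternatives inside the pooled clusters other than equal cell numbers, those on nucleosome distances, the clustering without depth-correlated components, the one without marker regions and the one with at least 1000 fragments were chosen only after the data were seen. No paired analysis was possible because each group has 1 library. Motif classes, CTCF phasing, GC corrections and clustering without CTCF motif regions were not run. For values that moved, the cause was not tested unless stated.

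The germinal center-like share stayed lower in the knockout library under all 13 alternatives, but its knockout value moved in each. It was 1.17% at the lower and 0.197% at the higher clustering resolution, 1.40%, 0.987%, 1.35% and 1.246% with other seeds, 0.321% with thinned cells, 0.365% with at least 5000 fragments per cell, 1.57% with the stricter doublet filter and 1.28% when placed on control clusters. Without depth-correlated components it was 0.197%, and without marker regions 1.40%. With at least 1000 fragments per cell in both libraries it was 4.06%, since this setting adds shallow knockout barcodes. Every other seed gave a higher value than the main 0.668%. The control share moved to 13.4% at the higher resolution, 18.7% with thinned cells, 18.2% with at least 5000 fragments and 13.7% without depth-correlated components. The antibody-secreting-like share moved to 0% in the knockout library with at least 5000 fragments (exact upper bound 0.0841%) and to 0.406% with at least 1000, and to 1.95% in the control library with the stricter doublet filter. Called knockout cells were 4384 with at least 5000 fragments.

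The knockout minus control share under 120 bp reversed over all barcodes, to 2.77 percentage points. It was -0.77 outside accessible regions, -1.22 with thinned cells and -1.14 with at least 5000 fragments. For 150 to 250 bp, the same 4 settings gave -3.22, -1.23, -1.76 and -1.40, and for 300 to 450 bp 1.85, 2.65, 2.22 and 2.06. With dense bins kept, the differences for 3 and 4 nucleosomes reversed to -2 and -2 bp.

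Promoters higher in the knockout library numbered 70 with windows of 250 bp, 365 with at least 50 fragments and 1019 with no minimum, and those lower 694 and 2942 at these minimums, as more promoters enter. Regions numbered 8068 higher and 7489 lower with at least 50 fragments. Regions lower were 2374 with fragments under 120 bp. In the pooled clusters that setting gave 2408 higher and 1604 lower, with fewer regions measured. The Smarca5 promoter ratio moved to -0.43 when scaled to the rest of the gene. Gene list medians in 34 alternatives in whole libraries and 17 in the pooled clusters moved from the main value by less than 0.5 of the width of the random lists' central 95%. With the gene activity window in whole libraries, the memory list came to percentile 73.4, and T cell (99.99), interferon (98.8), antigen presentation (2.19) and germinal center (0.29) lay outside the central 95%, as did T cell (99.2) and myeloid (98.4) in the pooled clusters. Of 673 alternatives for named promoters in whole libraries 50 moved, and of 332 in the pooled clusters 20 moved, and none reversed. Depth limits the ratios of regions with few fragments, such as those with 1 fragment in the knockout library.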

Other observations

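The values in this part were chosen only after the data were seen. Regions typical of germinal center-like cells took 1.09% of region fragments in barcodes of the knockout library that were not called as cells, against 0.770% in its called cells. In the control library the values were 1.54% and 1.13%. The pooled clusters, which hold no germinal center-like cells, took 0.759% in the knockout and 0.677% in the control library. Called cells thus lay close to the pooled value in the knockout library and well above it in the control library. Barcodes not called as cells lay above it in both. The origin of their fragments was not tested.

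Control cells of clusters 0 and 4, which hold mostly knockout cells, numbered 48 among those set aside and carried 40.6% of the region difference but 4.44% of the dinucleosome difference. Antibody-secreting-like cells were 4.26% of control cells with Xist fragments only and 1.41% of those with Y fragments only.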
